A study of Homo sapiens with 2 samples.

How the data were processed

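Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in Z-138 cells. Z-138 is an established human mantle cell lymphoma line, a malignancy of mature B cells. The 2 libraries came from cells carrying a control shRNA and from cells carrying an shRNA against SMARCA4, 1 library each, and both were grown with doxycycline per the labels' protocols. Libraries were made from lysed cells with a Nextera kit, per the labels' protocols. Each library's group was taken from its genotype label.

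Each library came with 1 peak list of 10 columns. The submitters' processing notes name bcl2fastq 2.17.1.14, BWA, MACS2 and the genome build hg19, with no parameters, and versions of BWA and MACS2 are not given in the sources used here. Peak names in both lists contain the terms sort, rmdup and DMSO; the first pair of terms usually stands for sorted alignments with duplicates removed, and DMSO is a common solvent control. The names in the control list hold the term sort once more than those in the knockdown list. How insertion sites were shifted, and how mitochondrial reads and artefact-prone regions were treated, is not given in the sources used here. Peaks were called in each library separately, since every list carries its own peak names. The deposited fold is the ratio of the reads stacked at the summit to the expected background, each with 1 read added. The deposited −log10 p and −log10 q values are those of the peak caller for the summit. The largest deposited q-value was 0.0479 in the control library and 0.0499 in the knockdown library. The deposited score was, for all 55259 control peaks and all 41611 knockdown peaks, 10 times the −log10 q-value without its decimals. These values belong to single peaks of 1 list and were used here to describe, rank or filter peaks within that list.

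The lists hold no read counts, but the fold and the p-value of a peak together fix the summit pileup (the number of reads or fragments stacked at the summit) and the expected background at the peak. Both were solved for every peak from a Poisson tail. The recovered whole-number pileups gave back the deposited −log10 p-values within 4.2e-05 in both lists. On peaks simulated from each library's recovered values, the pileup came back exactly for 55258 of 55259 control and 41606 of 41611 knockdown peaks. The lowest background was 0.24 reads in the control and 0.322 reads in the knockdown library. All 43837 control and 35507 knockdown background values above it were whole numbers of reads per 10 kb, within a tolerance of 0.02 reads. The shortest peaks, 94 bp in the control and 89 bp in the knockdown list, were taken as the extension length that the caller used. These values give a read number 1.42 times as high in the knockdown library as in the control. Under an assumed effective genome size of 2.7 Gb they correspond to 6.89 M and 9.76 M reads or fragments. The read number is that of the whole alignment used for calling, so reads that map to no chromosome analysed here may be part of it.

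Peaks on chromosomes 1 to 22 and X were kept, and those on chromosome Y were left out. Overlapping peaks of 1 list were to be merged to regions; there were 0 such overlaps in either list, so each region is 1 deposited peak. A region counted as overlapped when at least 1 bp of it lay in a region of the other library. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error over regions only. Reads from amplified libraries without molecular identifiers are not independent molecules, and neighbouring regions are not independent. With 1 library per group no test between groups can be made, and no p-value between groups is given. Whether a difference exceeds the spread between cultures, or between repeat libraries of 1 culture, cannot be judged from these data. Chance overlap was measured by moving every region 1 Mb up or down its chromosome.

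Weak peaks are lost first when fewer peaks are called, so overlapped shares were also compared with the share given by strength. For this, the regions of a library were put in 13 bands of deposited fold. The overlapped share of each band over the whole genome was averaged over the regions of interest. Alternatives used 15 bands of recovered summit pileup, or the fold bands split into 4 width classes. Windows of 5 Mb with at least 40 control regions were compared the same way.

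Before the data were examined, the rule for named regions was fixed as the 6 control-only and the 6 knockdown-only regions with the highest deposited fold in their own library. Also fixed then were 16 gene lists, 19 sequence motifs and a comparison of promoters with distal regions. None of these could be run: a gene annotation and genome sequence of the build hg19 were not used here, and the gene table at hand is of GRCh38, whose coordinates cannot be set against hg19 positions. Regions are therefore given by hg19 coordinates, counted from 1, without gene names. The choices tried beside the main settings were q-value limits of 0.001 and 1e-05, lists of equal length, overlap of 50% of a region or of both regions, and a gap of up to 500 bp. A fold of 5 or 10 in both lists, the fold of 12 for strong regions, the comparisons by chromosome, window and spacing, and the pileup and width bands were chosen after the data had been seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; plots used matplotlib 3.10.9.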

Results

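Accessible chromatin was mapped in 2 libraries of the mantle cell lymphoma line Z-138, 1 with a control shRNA and 1 with SMARCA4 knocked down. SMARCA4 is a catalytic ATPase of the SWI/SNF chromatin remodelling complexes, which move nucleosomes and open chromatin. The series' design ties the knockdown to the response of mantle cell lymphoma cells to ibrutinib, an inhibitor of the kinase BTK, together with venetoclax, an inhibitor of BCL2. The labels of the 2 libraries name no treatment with either drug. The comparison is between the sets of accessible regions found in the control and in the knockdown library. Neither list gives read totals. The depth recovered from the caller's values was 6.89 M reads or fragments in the control and 9.76 M in the knockdown library, under an assumed genome size of 2.7 Gb. The lowest summit that entered a list had 3 stacked reads in the control and 4 in the knockdown library. A region outside a list is therefore one below the caller's limit, not one shown to be closed. The knockdown itself was not checked here, since a peak list measures neither SMARCA4 RNA nor protein.

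The knockdown library held fewer accessible regions than the control library. On chromosomes 1 to 22 and X, 55124 regions were called in the control and 41540 in the knockdown library, which is 75.4% of the control number (95% counting interval 74.4 to 76.3%). Control regions covered 11.4 Mb of the genome, and knockdown regions covered 9.37 Mb, or 82.0% of that length. Median widths were close in the libraries, at 161 bp in the control and 163 bp in the knockdown (interquartile ranges 111 to 246 bp and 112 to 272 bp). Wide regions were more numerous in the knockdown list, which held 2014 of 600 bp or more against 1476 in the control list. The authors' fold enrichment had a median of 6.45 in the control list and 7.04 in the knockdown list. The recovered summit pileup had a median of 8 reads in the control and 10 reads in the knockdown library. The deficit varied with enrichment, and not in a single direction. At a fold of at least 5 the knockdown list held 35087 regions against 39918, or 87.9%, and at a fold of at least 10 it held 9589 against 10321, or 92.9%. At a fold of at least 15 there were 1641 knockdown and 1864 control regions, or 88.0% (82.3 to 94.1%). At a fold of at least 20 there were 116 and 195, or 59.5% (46.9 to 75.2%). Folds rest on the background of their own list, which was higher in the knockdown library. The 1 read added to summit and background also lowers the fold more in the shallower control library. At equal enrichment over background a fold limit is therefore laxer in the knockdown list, so these percentages do not compare regions of like strength.

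Most regions of the knockdown library were also regions of the control library, and the converse held less often. A knockdown region overlapped 33358 of the 55124 control regions, or 60.5% (60.1 to 60.9%). A control region overlapped 32992 of the 41540 knockdown regions, or 79.4% (79.0 to 79.8%). This left 21766 control-only and 8548 knockdown-only regions. After all regions were moved by 1 Mb, 0.664 to 0.684% of control and 0.879 to 0.93% of knockdown regions were overlapped by chance. With both lists reduced to 41540 peaks of highest significance, the overlapped shares were 71.7% in the control and 71.6% in the knockdown list. Lists of equal length give nearly equal shares by construction, so this pair of values shows the extent of overlap and not which library lost regions. Overlapping regions had their summits close together, with a median distance of 28 bp over 33358 pairs (interquartile range 11 to 56 bp).

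Regions found in 1 library were mostly weak and narrow. Control-only regions had a median fold of 4.95 and a median width of 117 bp, against 7.91 and 202 bp for control regions with a partner. Knockdown-only regions had medians of 5.30 and 106 bp, against 7.87 and 185 bp. Of the control-only regions, 31.6% had the smallest width in the list, against 5.42% of those with a partner; the corresponding shares in the knockdown list were 32.0% and 6.53%. Among control regions with a fold below 4, 17.7% were overlapped, and this share was 66.7% at folds from 6 to 8 and 98.9% at folds of 15 or more. All 1476 control regions of 600 bp or wider had a knockdown partner, with a lower bound of 99.8% for that share.

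**Figure D1:**
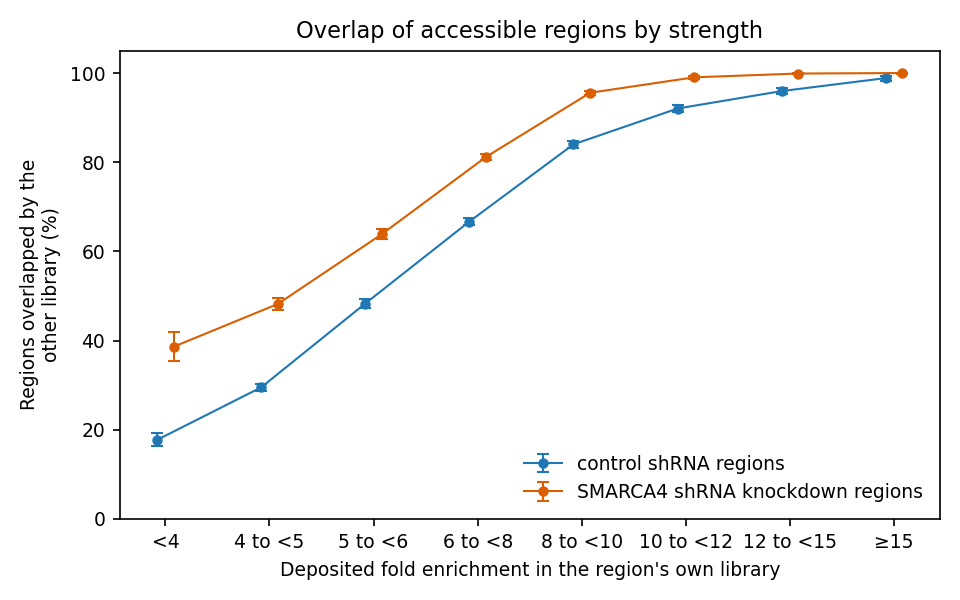
Share of regions overlapped by the other library (y axis, percent) by the deposited fold enrichment in the region's own library (x axis, 8 bands). Points are the 55124 control and 41540 knockdown regions, bars are exact binomial 95% intervals, and the control curve reaches 98.9% in the strongest band against 100% for the knockdown curve.

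Among strongly enriched regions, control regions without a knockdown partner outnumbered knockdown regions without a control partner. At a fold of at least 12, 171 of 5569 control regions had no knockdown partner, or 3.07% (2.63 to 3.56%). In the knockdown list, 4 of 5301 regions of that fold had no control partner, or 0.0755% (0.0206 to 0.193%). At a fold of at least 15 these numbers were 21 of 1864 control regions and 0 of 1641 knockdown regions, the latter with an exact upper bound of 0.225%, or 0.183% by a limit of 3 counts. The knockdown library had the higher recovered read number. The counts were 452 and 80 when a partner had to cover 50% of the region, and 604 and 241 with 50% of both. With lists of equal length they were 171 and 15, and with q-values of at most 1e-05 in both lists 327 and 24. The size of the imbalance thus depends on the overlap rule and on the limits of the lists.

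The strongest control-only region lay on chromosome 8 from 60489422 to 60489758 (hg19), with a fold of 19.2 and a summit pileup of 33 reads. Its nearest knockdown region was 141 kb away. The next was on chromosome 13 from 58520592 to 58520809, with a fold of 18.5, 32 reads and a nearest knockdown region at 199 kb. A region on chromosome 11 from 83473650 to 83473975 had a fold of 17.3 and 29 reads. A second region on chromosome 13, from 109924366 to 109924559, had a fold of 16.8 and 25 reads. The region on chromosome 14 from 52205535 to 52205786 had a fold of 16.6 and 22 reads. The region on chromosome 3 from 178198632 to 178198889 had a fold of 16.5 and 24 reads. Scaled to the depth of the knockdown library, these 6 summits correspond to between 29.5 and 44.3 reads. Within 50 kb of the 6 regions the control list held 7 further regions, of which 3 had a knockdown partner. Over all control regions this share was 60.5%.

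The strongest knockdown-only regions had lower folds, and most lay near regions that both libraries shared. The first, on chromosome 4 from 113021137 to 113021344, had a fold of 13.2 and 19 reads, but a control region began or ended 52 bp away from it. The region on chromosome 8 from 2075669 to 2075847 had a fold of 13.2, 17 reads and its nearest control region 28.7 kb away. On chromosome 4, the region from 88894871 to 88895019 had a fold of 13.1 and 21 reads, with a control region at 1.74 kb. The region on chromosome 3 from 111805054 to 111805288 had a fold of 12.8 and 22 reads. On chromosome 7, the regions from 52227270 to 52227404 and from 105683322 to 105683494 had folds of 11.9 and 11.8, each with 17 reads. Within 50 kb of these 6 regions, 20 of 24 other knockdown regions had a control partner, where 79.4% of all knockdown regions had one. Scaled to the shallower control library, the 6 summits correspond to between 12.7 and 16.4 reads.

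The top regions of each list were present in the other. The highest control fold, 28.4, was on chromosome 15 from 20747071 to 20747287, where the knockdown list had a region with a fold of 21.9 in its own library. The highest knockdown fold, 24.3, was on chromosome 2 from 42067902 to 42068369, where the control list had a region with a fold of 19.4. These regions were chosen for their rank after the values had been seen. Folds of separate lists rest on separate backgrounds, so the values are given side by side and not as a change.

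Control regions on chromosome 19 were overlapped by knockdown regions more often than their strength would give, and regions on chromosomes 2, 3, 4, 5 and 13 less often. Chromosome 19 is known for its high gene density. On it 1101 of 1524 control regions had a partner, or 72.2% (69.9 to 74.5%), against 57.6% given by their fold enrichment. With reciprocal overlap of 50%, this excess fell from 14.6 to 7.91 percentage points (5.37 to 10.4). The shares were also above those given by fold on chromosome 17 (63.7% against 57.0%), chromosome 16 (63.9% against 58.7%), chromosome 22 (61.7% against 53.8%), chromosome 20 (58.8% against 55.0%) and chromosome 6 (62.4% against 60.6%). Below it were chromosome 4 (58.9% against 62.5%), chromosome 13 (58.6% against 62.0%) and chromosome X (55.6% against 58.4%). Also below were chromosome 2 (58.2% against 60.4%), chromosome 3 (59.1% against 61.6%) and chromosome 5 (58.3% against 61.0%). Of the 23 chromosomes, 12 lay outside the counting interval, where about 1.15 would by counting error alone. With strength measured by summit pileup, chromosome 6 and chromosome X no longer stood apart, while chromosomes 7, 11 and 15 did. With fold and width together, chromosome 20 no longer stood apart, while chromosome 21 did. The remaining 9, chromosomes 2, 3, 4, 5, 13, 16, 17, 19 and 22, kept their direction under each of these measures. In the opposite comparison, the shares of knockdown regions with a control partner lay outside the interval on 2 of 23 chromosomes by fold, 8 by pileup and 1 by fold and width, so the number depends on the strength measure.

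**Figure D2:**
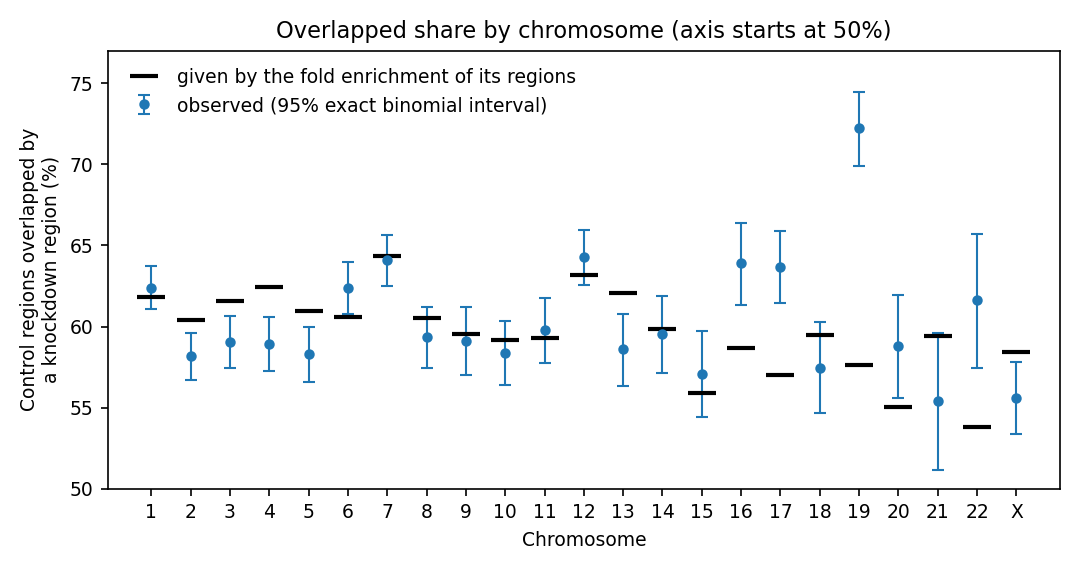
Share of control regions overlapped by a knockdown region (y axis, percent, starting at 50%) on each chromosome (x axis). Points are observed shares with exact binomial 95% intervals and horizontal marks are the shares given by fold enrichment; chromosome 19 stands at 72.2% against 57.6%.

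The number of regions also differed between chromosomes. Chromosome 19 had 1328 knockdown regions, 87.1% of its control number (80.9 to 93.9%), and chromosome X had 1318, or 67.7% (63.1 to 72.7%). In windows of 5 Mb with at least 40 control regions, 45 of 565 lay above the share given by fold and 24 lay below. Counting error alone would give about 14.1 on either side. Of the 11 windows on chromosome 19, 9 were above and 0 below. Its first window, from 0 to 5 Mb, had a partner for 145 of 187 control regions, or 77.5% against 54.0%. The window from 30 to 35 Mb of chromosome 6 had partners for 131 of 176 regions, or 74.4% against 58.4%. At the other end, the window from 140 to 145 Mb of chromosome 2 had partners for 29 of 77 regions, or 37.7% against 58.1%. The window from 90 to 95 Mb of chromosome 9 had partners for 24 of 73, or 32.9% against 51.8%. These windows were singled out after their values had been seen.

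In the control list, isolated regions were overlapped less often than regions that lay close to another. Of 1895 regions with the next one at least 100 kb away, 947 had a knockdown partner (interval of the share 47.7 to 52.2%), against 58.0% given by fold and 53.5% given by summit pileup. Of 9368 regions with another within 500 bp, 72.0% had one (71.1 to 72.9%), against 57.7% given by fold and 67.3% given by pileup. The isolated regions stayed below the share given by fold under every overlap rule tried, but the size varied. With reciprocal overlap of 50% their difference from that share went from -8.03 to -4.93 percentage points (-7.16 to -2.67). The excess of the close regions did not hold under every rule: with reciprocal overlap of 50% their excess of 14.3 percentage points over the share given by fold became -0.672 (-1.68 to 0.343). Between 500 bp and 5 kb the observed shares were above those given by fold and below those given by pileup, so no direction is given for them. The observed shares of the knockdown list did not show this order. A control partner was found for 77.6% (75.9 to 79.2%) of its isolated regions and 75.9% (74.9 to 76.8%) of its regions within 500 bp of another. Its isolated regions lay below the 79.7% given by fold and above the 75.4% given by pileup. Its regions within 500 bp of another lay above the 74.1% given by fold and below the 82.7% given by pileup. The order was thus present relative to fold and reversed relative to pileup.

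**Figure D3:**
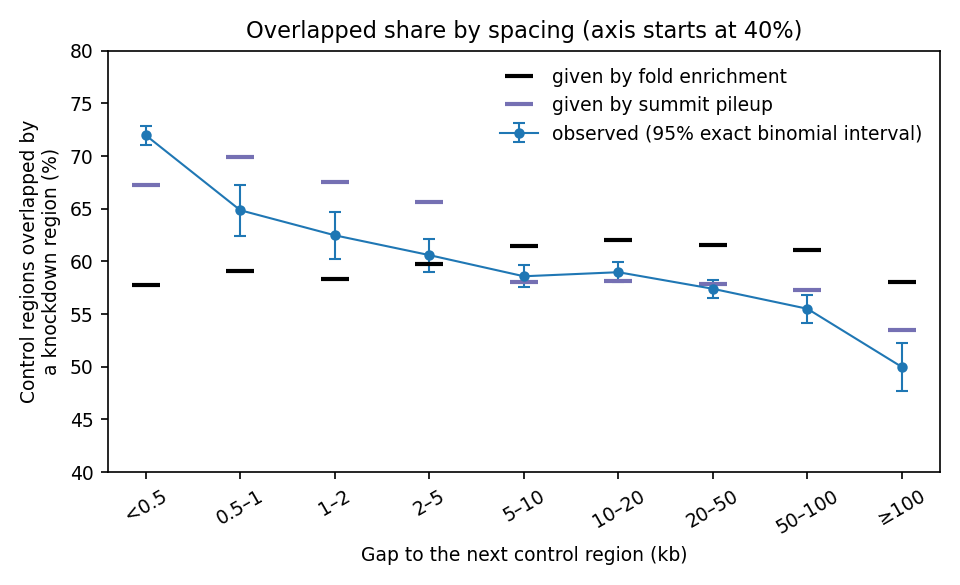
Share of control regions overlapped by a knockdown region (y axis, percent, starting at 40%) by the gap to the next control region (x axis, kb). Points are observed shares with exact binomial 95% intervals, and marks show the shares given by fold and by summit pileup; regions at least 100 kb from the next lie below both marks, of 58.0% and 53.5%.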

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

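Leaving out a replicate was not possible with 1 library per group, and the promoter, gene list and motif comparisons were not run, with all their alternatives, for want of an hg19 annotation and sequence. Fold limits and pileup or width bands were chosen after seeing the data. Knockdown regions as a share of control regions rose from 75.4% to 81.7% at a q-value of at most 0.001, 84.8% at 1e-05, 87.9% at a fold of 5 and 92.9% at a fold of 10; it stayed at 75.4% without merging, and lists of equal length give no value by construction. The covered length was 82.0% and passed equality only at a fold of 10, at 100.2%. A fold limit is laxer in the deeper knockdown list, so values at fold limits may overstate what the knockdown list held. The share of control regions overlapped was 60.5% and became 64.9% at a q-value of 0.001, 66.8% at 1e-05, 68.4% at a fold of 5, 71.7% with lists of equal length, 76.2% with the 1e-05 limit on control regions alone, 54.6% with 50% overlap, 49.0% with reciprocal overlap and 64.2% with a 500 bp gap. For knockdown regions the share was 79.4%, and the matching settings gave 78.7%, 78.2%, 77.1%, 71.6%, 89.2%, 73.9%, 65.0% and 84.4%. Here the 89.2% has the 1e-05 limit on knockdown regions alone. Beyond the construction of equal lists, the cause of these shifts was not tested. Strong control-only regions, 171 at a fold of 12, numbered between 171 and 604, and strong knockdown-only regions, 4 in the main setting, between 3 and 241; the former were the larger number under all 8 alternatives. Of the 12 named regions, 1 had a region of the other library within 500 bp. The excess on chromosome 19, 14.6 percentage points, ranged from 7.91 to 17.1. The deficit of isolated regions ranged from -11.0 to -3.55. The excess of regions within 500 bp of another, 14.3, reversed with reciprocal overlap to -0.672 (-1.68 to 0.343, an interval that includes 0), was 4.72 with pileup bands and reached 27.0 with a 500 bp gap; the cause was not tested. The lowest summits called had 3 or 4 reads, and median summits were 6 reads in control-only and 7 reads in knockdown-only regions. Weak regions found in 1 list therefore stay undecided, and for how many of them depth is the reason was not counted.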

Other observations

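The tests on read number, on signal in 1 preparation, on local-read scaling, on uniform lowering, on peak strength and on sequence bias were chosen after the result was seen; the tests on the calling limit and on neighbouring regions were set before their values were computed.

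At regions present in both lists, more reads were stacked in the knockdown library, but fewer than its depth would give. Over 33358 pairs the recovered summit pileup of the knockdown was a median 1.13 times that of the control. Recovered read numbers and extension lengths together would give 1.34 times. Scaled by depth, the median log2 ratio of knockdown to control was -0.25 (95% interval of the median -0.25 to -0.24, interquartile range -0.62 to 0.08). Scaled to the reads of the surrounding 10 kb it was -0.13 (-0.14 to -0.12) over 27933 pairs. These medians rest on different sets of pairs, so their difference may come from the scaling, the pairs or both. That 10 kb count was not freed of the region's own reads, which would make the shortfall look smaller. By depth, chromosome 19 had a median of -0.10, chromosome 22 of -0.13, chromosome 17 of -0.14 and chromosome 16 of -0.15, while chromosome 4 had -0.33 and chromosome 21 had -0.31. Chromosomes 16, 17, 19 and 22, with the smallest fall in pileup, were also among those with overlapped shares above the share given by strength. Both measures rest on the knockdown signal at control regions, so this match is partly built in and gives no separate support. Pairs are chosen for being in both lists, so these medians leave out the regions lost from either list.

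The first pattern is the lower number of regions in the knockdown library. A lower read number is argued against by the recovered read numbers, with a ratio of knockdown to control of 1.42, and by the reads in the 10 kb around 27933 shared regions, with a median ratio of 1.29. A stricter calling limit could be set by the higher background of the deeper library. Alone, it would give a median log2 depth-scaled pileup of 0 or more in regions chosen as strong in the knockdown list. The median was -0.13 (-0.14 to -0.12), below that bound. This value rests on the expected pileup ratio of 1.34, which follows from the read ratio of 1.42 and the extension lengths. The read ratio may count reads outside the chromosomes analysed. An overstated ratio would itself give such a shortfall. Scaled instead to the reads of the surrounding 10 kb, which needs no recovered depth, the median was only -0.01 (-0.02 to -0.00) in those regions. It was -0.08 (-0.09 to -0.07) in the 4186 pairs with the highest mean pileup of both libraries. The 10 kb count was not freed of the region's own reads, which would draw such ratios towards 0. The size of the shortfall thus depends on scaling and selection. The lowest summit called had 3 reads in the control, where the lowest background was 0.24 reads. In the knockdown library it had 4 reads, with a lowest background of 0.322. The lowest fold called was 3.04 in the control and 2.81 in the knockdown list. By these lowest calls the limit was not stricter in the knockdown list, but a minimum rests on single peaks. Whether the calling limit is the whole cause is not decided, and how many missing weak regions it accounts for was not counted. Less signal over background in a single preparation, with a median log2 ratio of -0.25 by depth and -0.13 by surrounding reads, cannot be told apart from an effect of the knockdown, because each group has 1 library.

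The second pattern is that strong regions missing from 1 list were mostly control regions, 171 against 4 at a fold of 12, though 604 against 241 with reciprocal overlap of 50%. A uniform lowering of signal with counting error alone would leave 55.0 such regions missing (up to 70) with every summit at 0.5 times the pileup expected from depth, below the observed interval of 147 to 198. That number rests on an assumed factor, an assumed calling limit and control summits chosen for being high, so this explanation stays open. Loss of whole stretches of chromosome, as a cause common to these regions, is argued against by their neighbours. Of 339 other control regions within 50 kb, 56.6% (51.2 to 62.0%) had a knockdown partner, against 61.0% given by their strength. This share pools the neighbours of all these regions, so loss round a minority of them would not show and stays open. The strongest control-only regions of chromosomes 8 and 13 had 0 other control regions within 50 kb, so nothing is decided there. Round the named control-only regions 3 of 7 such neighbours had a partner, too few to decide. Variation between libraries beyond counting, and a real closing of the strong control-only regions after SMARCA4 knockdown, both stay open and untested. No repeat library was at hand.

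The third pattern is the high overlapped share on chromosome 19. The mix of peak strengths gives 57.6%, outside the interval of the observed 72.2% (69.9 to 74.5%), which argues against it as the whole cause. A bias between the libraries in base composition, or in another property of sequence, could also favour gene-dense and GC-rich chromosomes. Knockdown regions there would then have a control partner less often than their strength gives, but the share was 81.0% (78.8 to 83.1%) against 79.6% given by fold, 78.5% by pileup and 82.6% by fold and width, so the reading changes with the strength measure and nothing is decided. This bias stays open, because region sequences were not used, and so does an effect of the SMARCA4 knockdown that differs between chromosomes, which was not tested.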
